A study of Drosophila melanogaster with 2 samples.

How the data were processed

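Total RNA of 2 samples of wild-type SL2 cells was labelled with biotin by a one-cycle protocol and read on Affymetrix GeneChip arrays, per the labels' protocols. The cells were untreated. The authors deposited 1 table with a log2 expression level per probe set and array. The submitters' processing notes name the package affy; its version, the background correction, the summary method and the genome build are not given in the sources used here. The log base is not stated either. It was taken as log2 from the values: read as natural logs, the highest would be 1115940 on a linear scale, beyond the 65535 that a 16-bit scanner can record, whereas as log2 it is 15556. The sorted columns of the deposited table differed by at most 0.092, as columns made alike by a normalization between arrays do. Such a step removes any overall difference in RNA content, so levels are relative to the whole array. A total of 246 probe sets had the same value on both arrays, and the others differed, so the arrays were kept as 2 samples.

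Gene names came from the platform annotation, which listed 14049 of the 18952 probe sets. Of these 13646 named 1 gene, 402 named several and 1 had no symbol; 4720 other probe sets and 183 control probe sets were unnamed here. Symbols were updated by gene ID through a RefSeq gene table of the Release 6 plus ISO1 MT assembly, which matched 13543 of the 13646. That table also gave each gene's chromosome arm and its neighbours; no coordinates are printed, because no build is known for the arrays. Only probe sets with 1 gene were used for genes. A gene's level was the mean of its probe sets, which gave 11981 genes, 1094 of them with more than 1 probe set. For 400 genes the probe sets lay on different sides of the floor.

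A gene was above the floor when its level on each array exceeded that array's 95th percentile of probe sets of olfactory and gustatory receptor genes. This is a rule, not a test, and by its construction about 5.36% of the receptor genes pass. The 30 gene lists, the floor, the rule for named genes and the alternatives were fixed before the data were examined. List names were matched to current symbols or, where unique, to synonyms; names without a probe set of 1 gene were left out. Genes named were the 10 of highest mean level, the 5 above the floor with the largest difference in each direction, the 2 highest and 2 lowest of each list, and any member of the dosage compensation, sex determination and homeotic lists. Others are said to have been named after their values were seen.

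List medians were placed among those of 10000 random gene lists of the same size, and differences between arrays among lists matched on mean level in 20 bins. The X was compared with arms 2L, 2R, 3L and 3R by the difference of median levels, computed per array, and placed among 10000 random gene sets. These percentiles describe the 2 arrays and are not p-values. The alternatives were a floor at the 99th percentile or at the median of all probe sets, the highest probe set per gene, only probe sets without the s, x or a suffix, quantile normalization, each array alone, no floor, and each autosome arm left out. A pseudocount on linear values was not tried, because the values were already log2. For a difference of a list between arrays, which has no replicates, an alternative was taken to move it when it did so by more than the half-width of the central 95% of random lists. For a simulation, each of the 11981 genes was given a level drawn from the genes of higher level, and no floor was applied. A shift of -0.4 on the X was recovered as -0.39 ± 0.05 (SD over simulations) and a shift of 0 as 0.005. This checks the difference of medians, not the effect of the floor on it. Of unchanged lists of 20 genes, 3.5% fell outside the central 95% for level and 2% for the difference, and all lists of 20 genes changed by 0.15 did. These simulations used the same noise at all levels. Many of the fixed lists are smaller, and how often a change in them would be found was not simulated. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.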

Results

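The series measured the RNA levels of all genes on an expression array in SL2 cells, a cell line that Schneider derived from late Drosophila melanogaster embryos and that is widely used for work on chromatin, immunity and RNA interference. It held 2 samples of 1 group, untreated wild-type cells in exponential growth. The labels do not say whether the 2 RNA samples came from separate cultures, so the spread between them may be technical. There was no second condition, and the comparisons open to the design were between sets of genes and between the 2 arrays. No p-value is given, because genes are not replicates and there was nothing to test between groups. Each array carried 18952 probe sets, whose levels ran from 2.04 to 13.92 on sample 1 and from 2.12 to 13.93 on sample 2 on the log2 scale. Errors are SDs over the 2 arrays, a number that limits their precision. Probe sets differ in how strongly they bind their target, so the level of a single gene is not read here as more or less RNA than that of another gene.

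The first question was which genes the cells expressed. Of 11981 genes with a level of their own, 6732 (56.2%) lay above background on both arrays, and 5249 did not. Background was set by the olfactory and gustatory receptor genes, a family used by sensory neurons, as the 95th percentile of their 125 probe sets, which was 3.97 on sample 1 and 3.85 on sample 2. By this floor 6 of 112 receptor genes (5.36%) were themselves above background, a share that the definition of the floor sets and that is not a measured rate. The highest receptors were Gr61a at 6.78 ± 0.11 (SD, n = 2) and Gr5a at 4.95 ± 0.21, and the lowest were Or67d at 2.52 ± 0.05 and Or13a at 2.55 ± 0.07. The 10 genes of highest level were RpL41, RpS18, RpLP1, RpS26, RpL23, RpL37-1, RpL15, RpS15, RpS20 and tsr. The first 9 encode ribosomal proteins, and tsr encodes cofilin, which severs actin filaments. Their mean levels ran from 13.70 (tsr) to 13.89 (RpL41), near the top of the scale, where arrays lose resolution. A floor at the 99th percentile of the receptors (4.73 and 4.95) left 5653 genes above it.

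**Figure D1:**
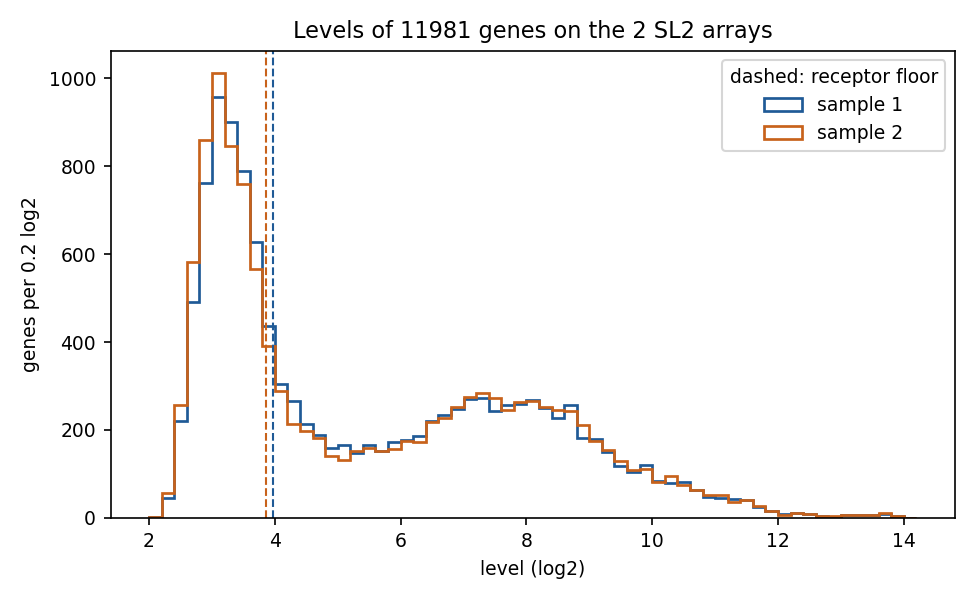
Number of genes per 0.2 log2 of level on sample 1 (blue) and sample 2 (orange), with the receptor floor of each array as a dashed line of the same colour. On both arrays the genes form a narrow peak below the floors of 3.97 and 3.85 and a broad one above them.

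Listed genes of growth and division were above background. Every measured member of these lists passed the floor: 32 cytosolic ribosomal protein genes, 69 mitochondrial ribosomal protein genes, 25 proteasome genes, 7 translation factors, 9 glycolytic enzymes, 14 DNA replication genes and 8 mitotic regulators. Not measured here were 6 proteasome, 6 translation, 3 glycolytic, 5 replication and 7 mitotic names, with CycA, Cdk1 and polo among the mitotic ones. The cytosolic ribosomal list, set by a pattern of symbols, does not hold every such gene on the array and leaves out RpL37-1. The cytosolic ribosomal list had a median of 13.52 ± 0.02 (SD, n = 2), the proteasome list 10.44 ± 0.01, the mitochondrial ribosomal list 8.83 ± 0.02 and the replication list 7.70 ± 0.04. The first 3 medians exceeded those of all 10000 random gene lists of the same size, and the replication median exceeded 98.7% of them. Among the examples, eIF4A, an RNA helicase of translation initiation, stood at 12.65 ± 0.001, and Gapdh1 of glycolysis at 11.68 ± 0.01. PCNA, the sliding clamp of DNA polymerase, stood at 11.05 ± 0.02, and CycB, a mitotic cyclin, at 9.46 ± 0.03. The ribosomal list also held the paralogs RpS5b (5.44 ± 0.12) and RpS28a (5.91 ± 0.07), its lowest members. The lowest mitotic gene was fzy, an activator of the anaphase-promoting complex, at 4.94 ± 0.06 as the mean of 3 probe sets, the highest of which read 8.48. With the 99th percentile floor 7 of the 8 mitotic regulators passed. All 7 heat shock genes measured were above the floor, with the constitutive chaperone Hsc70-4 at 13.09 ± 0.001 and the inducible Hsp68 at 8.05 ± 0.12. The other 9 names of that list, the Hsp70 genes and Hsp83 among them, were not measured here.

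Hemocyte markers were mostly above background, and so were genes of innate immunity. Of 19 hemocyte markers 15 passed the floor, with a list median of 8.22 ± 0.01 (SD, n = 2) that exceeded 99.97% of random lists. SPARC, a basement membrane protein, stood at 13.33 ± 0.01 and the secreted peptide gene Nplp2 at 13.17 ± 0.02. Named after their values were seen, the blood cell GATA factor gene srp stood at 9.87 ± 0.23, the clotting gene Hml at 8.22 ± 0.01 and the phagocytic receptor gene eater at 8.42 ± 0.06. The 4 markers not above the floor were gcm (2.94 ± 0.02), gcm2 (2.98 ± 0.32), He (3.07 ± 0.13) and NimC1 (3.58 ± 0.14), the last 2 also named after their values were seen. Of 8 crystal cell and lamellocyte markers 5 were above the floor, and the list median exceeded 62.2% of random lists. They were mys (10.01 ± 0.05) and cher (9.08 ± 0.02), which other tissues also use, and, named after their values were seen, PPO3 (7.21 ± 0.04), PPO2 (6.22 ± 0.01) and atilla (4.51 ± 0.10), whereas lz, the crystal cell regulator, was at 2.63 ± 0.05.

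All 17 measured genes of the Toll, Imd and JAK-STAT pathways passed the floor, from the Toll ligand gene spz (10.94 ± 0.0002) and the NF-kB gene Rel (10.14 ± 0.01) down to Dif (4.82 ± 0.07) and PGRP-LE (4.51 ± 0.20). With the 99th percentile floor 15 of the 17 passed. Of 6 antimicrobial peptide genes 5 were above background in these untreated cells. DptB stood at 12.29 ± 0.01, AttD at 11.81 ± 0.02 and CecB at 6.79 ± 0.02. Drs at 11.26 ± 0.06 and Mtk at 10.97 ± 0.05 were named after their values were seen. Def, at 3.88 ± 0.24, was above the floor on sample 1 and below it on sample 2. The list median of 11.11 ± 0.05 exceeded all 10000 random lists. It rests on 6 genes, since 8 other names of the list had no probe set of their own here.

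Markers of other differentiated cells ranged from lists wholly below the floor to 66.7% above it (glia), against 56.2% of all genes. None of 14 neuron markers, 13 muscle markers or 4 homeotic genes measured was above the floor. Not measured here were 2 neuron, 6 muscle and 8 photoreceptor names, with Mhc and Mef2 among the muscle ones. The same held for 4 fat body, 4 gut, 1 eggshell and 1 glia names. The highest neuron marker was elav, an RNA-binding protein gene, at 3.76 ± 0.05, and the highest muscle marker the actin gene Act79B at 3.80 ± 0.10. With the highest probe set of each gene, 1 neuron gene (brp, of the synaptic active zone) and 1 muscle gene (Mlp60A) passed, both named after their values were seen. The list medians exceeded those of 0.12% (neuron), 0.09% (muscle), 1.75% (homeotic), 0% (testis), 0.04% (cuticle), 0.47% (photoreceptor) and 2.12% (glue) of random lists. For other lists the shares were 26.9% (fat body), 31.7% (gut), 35.7% (eggshell) and 66.3% (glia). The homeotic genes were pb (3.33 ± 0.04), Dfd (3.30 ± 0.12), Antp (2.67 ± 0.08) and Scr (2.60 ± 0.04), and 4 others were not measured by a probe set of their own. Of 21 male germline genes 3 passed, which were mia (7.09 ± 0.06), a testis transcription regulator, Mst98Ca (4.68 ± 0.07) and, named after its value was seen, fzo (3.98 ± 0.10), while the spermatid gene dj was at 2.50 ± 0.02. Of 10 photoreceptor genes 2 passed, trpl (5.42 ± 0.13) and Arr2 (4.63 ± 0.07). Of 81 cuticle protein genes 23 passed, with Ccp84Ae highest at 6.04 ± 0.08. Of 10 salivary glue genes Sgs1 (4.38 ± 0.003) and Sgs5 (4.42 ± 0.10) passed. The 5 of 10 eggshell genes that passed were Cp38 (4.88 ± 0.01), Cp18 and, named after their values were seen, Cp36, Vm26Aa and Vm34Ca. Of 6 fat body genes 3 passed, namely Fbp1 (4.34 ± 0.19), Lsp2 and, likewise named afterwards, Yp2. Of 9 gut enzymes 4 passed, namely LManII (5.42 ± 0.08), epsilonTry and, also named afterwards, betaTry and Jon25Bi. Under the 99th percentile floor the counts were 9 for cuticle, 2 for gut, 1 each for testis and photoreceptor, and 0 for glue, eggshell and fat body. Of 6 glia markers 4 were above the floor, with loco (9.59 ± 0.02) and moody (9.21 ± 0.09) highest and, named after their values were seen, nrv2 (6.84 ± 0.08) and Gs2 (4.52 ± 0.01). Without probe sets shared between transcripts or genes the count was 1 of 3. Among the others was the glial regulator gene repo at 2.82 ± 0.22.

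**Figure D2:**
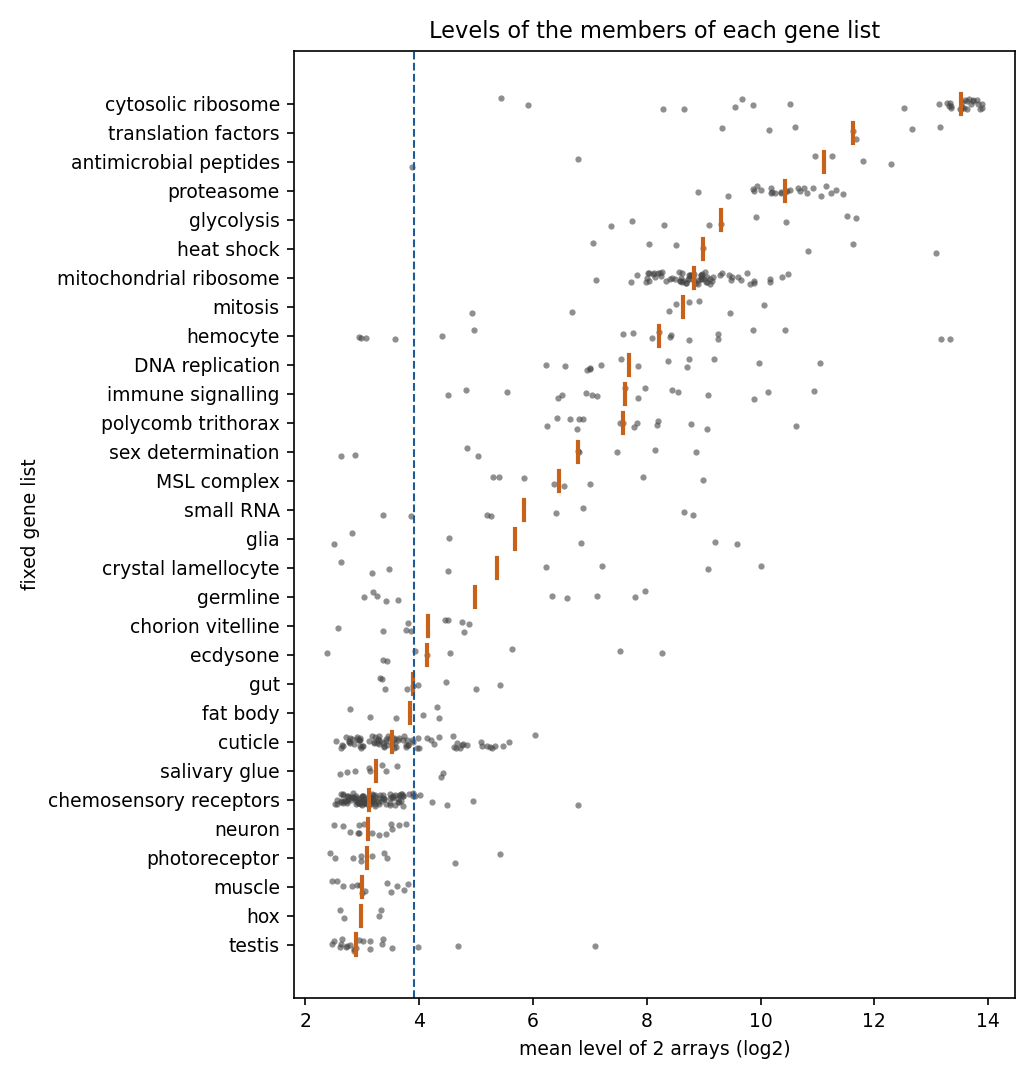
Mean level over the 2 arrays (log2, horizontal axis) of each measured member (points) of the fixed gene lists (vertical axis), with list medians as orange bars and the mean receptor floor as a dashed line. Cytosolic ribosomal genes have the highest median (13.52), and the neuron, muscle and homeotic lists lie wholly below the floor.

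Genes of the male dosage compensation machinery were all above background. This machinery, the MSL complex, raises transcription of the single X of males, and SL2 cells are male in character. The levels were 7.94 ± 0.04 (SD, n = 2) for the histone H4 acetyltransferase gene mof, 7.01 ± 0.17 for the helicase gene mle and 6.54 ± 0.14 for msl-2, whose protein is made in males. They were 5.84 ± 0.11 for msl-1 and 5.40 ± 0.06 for msl-3. The linked factors stood at 8.99 ± 0.03 for Clamp, 6.37 ± 0.07 for the H3K36 methyltransferase gene Set2 and 5.30 ± 0.07 for the kinase gene JIL-1. The non-coding RNAs of the complex, roX1 and roX2, were not analysed here. The median of the list was 6.46 ± 0.10, higher than in 80.9% of random lists.

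In the sex determination list 7 of 9 genes were above the floor, with tra2 at 8.87 ± 0.01, fl(2)d at 8.14 ± 0.01, tra at 7.48 ± 0.002, ix at 6.80 ± 0.10 and vir at 6.79 ± 0.09. Sxl, the female switch gene, averaged 4.83 ± 0.05 over 3 probe sets, the highest of which read 6.24, and fru averaged 5.03 ± 0.05 over 7. Which transcripts these probe sets read was not analysed here. The genes dsx (2.62 ± 0.04) and her (2.87 ± 0.04) were not above the floor. All 15 measured Polycomb and Trithorax genes passed, from the nucleosome assembly gene Caf1-55 (10.63 ± 0.01) down to Pc (6.24 ± 0.20). Another 5 names of that list were not measured here. Of 8 small RNA genes 6 passed, among them aub (8.81 ± 0.01) and Dcr-2 (8.66 ± 0.03). The genes piwi (3.37 ± 0.13) and AGO3 (3.86 ± 0.27) did not, although AGO3 was above the floor on sample 2 alone. Dcr-1, AGO1 and AGO2 of that list were not measured here. Of 10 germline genes 5 passed, with tud (7.97 ± 0.06) and spn-E (7.79 ± 0.03) highest, then tej, stau and gcl, named after their values were seen. The germ cell helicase gene vas was at 3.03 ± 0.03. Of 9 ecdysone response genes 4 passed, which were the receptor partner gene usp (8.26 ± 0.11), MsrA (7.52 ± 0.02) and, named afterwards, ftz-f1 and Hr39, while Hr3 was at 2.38 ± 0.16. The receptor gene EcR, also named afterwards, was above the floor on sample 2 alone. With the highest probe set of each gene 6 of the 9 passed.

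X-linked genes were set against those of the autosome arms 2L, 2R, 3L and 3R, a comparison of interest in male cells with dosage compensation. A larger share of X-linked genes was above the floor, 1134 of 1873 (60.5%) against 5545 of 9950 (55.7%). The difference of 4.82 percentage points exceeded that of all 10000 random gene sets of the same size, whose highest was 4.75. With the 99th percentile floor it was 2.78 points. Among the genes above the floor, however, the X had the lower median level, 7.00 ± 0.05 (SD, n = 2) against 7.38 ± 0.03. The difference was -0.39 on sample 1 and -0.37 on sample 2, a mean of -0.38 ± 0.01, or 0.767 times the autosomal level. It lay below all 10000 random sets, whose lowest was -0.28. The arms themselves ran from 7.28 ± 0.02 (3L) to 7.52 ± 0.04 (2R), and the 33 genes above the floor on chromosome 4 had a median of 7.63 ± 0.13. None of the 4 measured genes placed on the Y here was above the floor. The direction depended on the filter: over all genes, with no floor, the X median was higher by 0.42 ± 0.03, which exceeded 99.2% of random sets (central 95% -0.29 to 0.33). In a setting added after the data were seen, with no floor but equal shares above it on the X and the autosomes, it was -0.21. The comparison is between different genes read by different probe sets and has no female or uncompensated cell beside it, so it gives no measure of compensation.

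**Figure D3:**
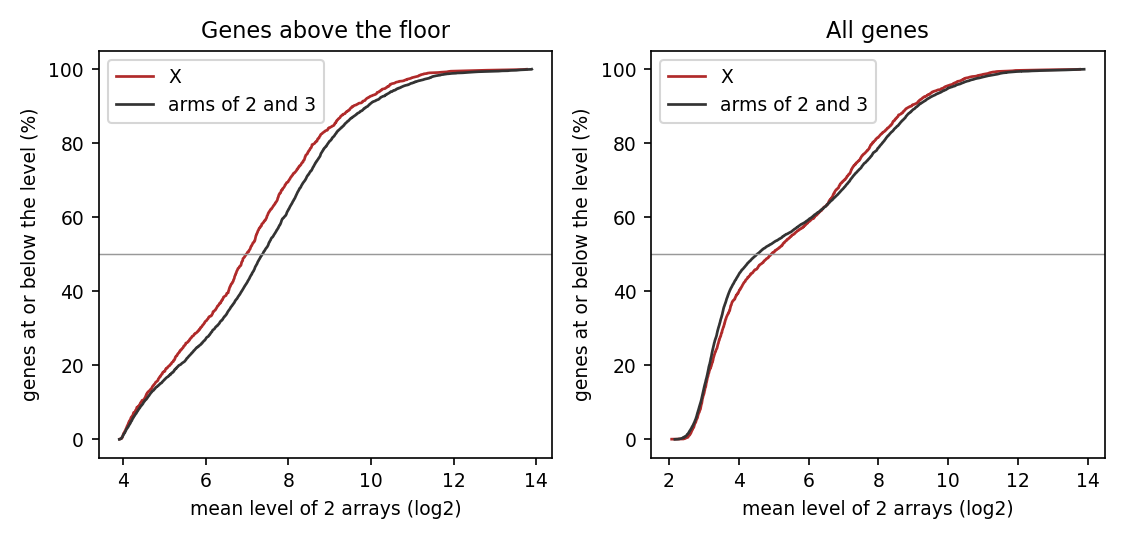
Cumulative share of genes (%) by mean level over the 2 arrays (log2) for the X (red) and the arms of chromosomes 2 and 3 (black), for genes above the floor (left) and all genes (right), with a grey line at 50%. At that line the X lies left of the autosomes among genes above the floor (6.99 against 7.38) and right of them over all genes.

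The last comparison was between the arrays. Across the 18952 probe sets they correlated with a Pearson r of 0.998 and a Spearman rho of 0.986, values taken across probe sets, which are not independent replicates. The difference, sample 2 minus sample 1, had an SD of 0.16 and a median of -0.004. Of 6732 genes above the floor, 16 differed by at least 0.5 and 0 by at least 1. The SD was 0.17 for probe sets at levels of 2 to 4, 0.20 at 4 to 6 and 0.06 at 10 to 14. The median difference changed sign with level, from -0.05 at 2 to 4 to 0.06 at 6 to 8, and was 0.01 at 10 to 14. Among genes above the floor on both arrays, the 5 furthest apart in each direction had mean levels from 4.22 (Bfc) to 5.76 (Vps53). Higher on sample 2 were CG13933 (by 0.87), the tethering complex gene Vps53 (by 0.63), loqs of the small RNA pathway (by 0.60), Pldn (by 0.60) and olf186-M (by 0.59). On sample 2 CG13042 read -0.59, CG13970 -0.51, CG17127 -0.49, CG7460 -0.48 and Bfc -0.48 relative to sample 1. Genes that crossed the floor between the arrays were not ranked. The ecdysone receptor gene EcR, named after its value was seen, was 1 of them. It was higher on sample 2 by 0.71 and above the floor there alone. With 1 array on each side these differences have no replicate check.

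Of the 30 lists, 3 had a median difference outside the central 95% of random lists matched on level, where 1.5 would lie by chance. They were the small RNA list (0.15, higher on sample 2, and 0.08 over members above the floor), the ecdysone list (0.10, higher on sample 2) and the cuticle list (-0.08, lower on sample 2, and -0.04 after quantile normalization). The medians of all lists lay between -0.08 and 0.15. The antimicrobial peptide list differed by 0.03 and the heat shock list by 0.06, both inside the range of random lists.

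**Figure D4:**
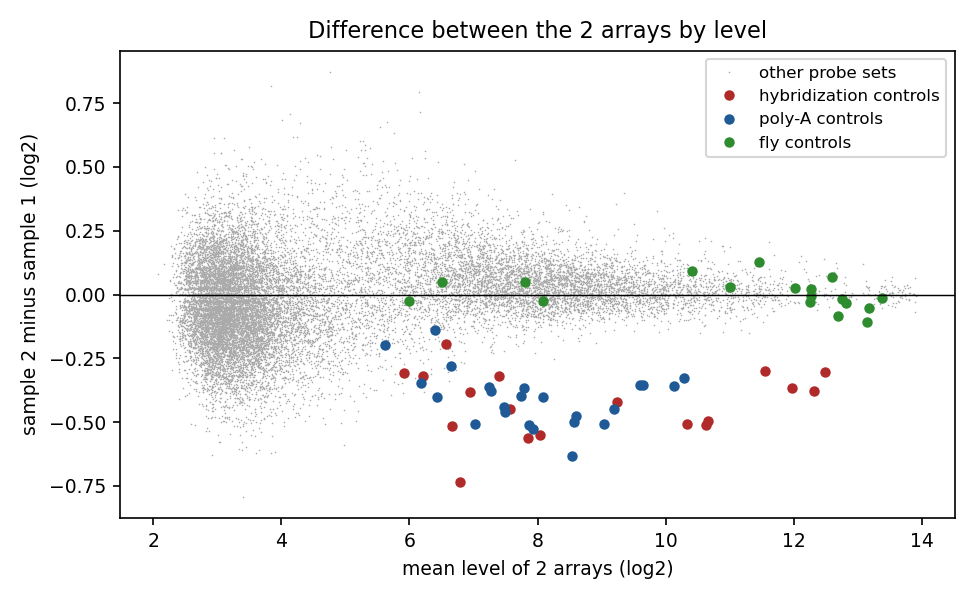
Difference between the arrays (sample 2 minus sample 1, log2) by mean level (log2) for each probe set (grey) and for the added hybridization controls (red), the added poly-A controls (blue) and fly actin, Gapdh and eIF-4a controls (green). The SD of the difference is 0.17 at levels of 2 to 4, 0.20 at 4 to 6 and 0.06 at 10 to 14.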

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

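The tests of control transcripts in this part were chosen after the result was seen. A signal appeared in control probe sets outside the gene comparisons: control transcripts of bacterial and phage origin read lower on sample 2 on all 42 probe sets. The median difference was -0.40 for the 18 hybridization controls (bioB, bioC, bioD and cre) and -0.40 for the 24 poly-A controls (dap, lys, phe and thr), against -0.01 for 18 probe sets of fly actin, Gapdh and eIF-4a. In the deposited values the gene probe sets nearest in level differed by a median of 0.036. A normalization between arrays would hold that value near 0. It therefore does not decide whether a shift shared by all probe sets was present before that step. A different amount of only 1 of the control mixes is argued against, as the medians of the classes differed by -0.0020 (95% bootstrap interval -0.13 to 0.10). That interval is over probe sets, several of which read the same transcript, so it does not measure the spread in the amounts added. More labelled fly RNA relative to both mixes on sample 2 may account for it and was not tested, nor was any biological explanation, because both samples belong to 1 group.

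A signal also appeared in probe sets that the annotation used here does not name. Of these 4720, 1105 (23.4%) were above the floor on both arrays, against 7413 of 13646 (54.3%) with 1 gene and 229 of 402 (57.0%) with several.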

How the results depend on the processing

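The settings of equal shares, of genes with 1 probe set, of fixed-list genes left out and of the floor without its highest receptor were chosen after seeing the data. The count of 6732 genes above the floor stayed within 1.5 times under every alternative run, from 5233 (probe sets without the s, x or a suffix, which measured 10074 genes) to 6947 (floor at the median of all probe sets). It was 6924 and 6813 for the arrays alone and 6841 with the floor without its highest receptor. The lower X median of -0.38 was 0.42, the other way, over all genes with no floor. It was -0.35 with the floor at the median, -0.41 with the highest probe set, -0.35 without the suffixes, -0.33 without arm 2R, -0.40 without 3L and -0.41 without 3R, and -0.35 to -0.39 for single arrays. It was -0.33 for genes with 1 probe set, -0.38 without the fixed-list genes, and -0.21 with no floor and equal shares above it. The excess of X-linked genes above the floor, 4.82 points, was 2.78 with the 99th percentile floor, 4.59 with the floor at the median, 5.11 with the highest probe set, 5.57 without the suffixes and 4.63 to 4.78 for single arrays. The 99th percentile floor left 1 photoreceptor, 0 fat body, 1 testis, 0 eggshell, 0 glue, 9 cuticle, 2 receptor and 2 gut genes. The highest probe set put 1 neuron and 1 muscle gene above the floor, and sample 2 alone 1 muscle gene (0 to 1 for single arrays). Without the suffixes fewer genes were measured, and the counts were 19 of 19 cytosolic ribosomal, 2 of 2 translation, 3 of 3 glycolytic, 5 of 5 dosage compensation, 4 of 6 sex determination, 9 of 9 Polycomb and Trithorax, 9 of 13 hemocyte, 4 of 4 heat shock, 1 of 3 glia and 1 of 8 photoreceptor genes. The SD of the difference between arrays was 0.14 above the floor and 0.16 (0.155) after quantile normalization. The list differences between arrays that moved were, after quantile normalization, 0 for mitochondrial ribosomal, -0.039 for cuticle and -0.011 for receptor genes. Over members above the floor they were -0.14 for photoreceptor, -0.27 for fat body, 0.082 for testis and -0.13 for receptor genes, with no value for the homeotic, neuron and muscle lists, which had 0 such members. In all, 256 values under alternatives were the same by these criteria, 44 moved and 1 reversed. The log2(value + pseudocount) alternative was not run, because the values were already log2. Where no cause is named above, the cause was not tested. No paired analysis was possible because there is only 1 group. Signal near background limits the lists close to the floor.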

Other observations

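The families named here, and the tests of equal shares, genes with 1 probe set, level cutoffs and shuffled gene order, were chosen after the result was seen. All 15 aminoacyl-tRNA synthetase genes were above the floor, as were 27 of 32 genes of respiratory complex I, 12 of 14 of ATP synthase and 24 of 34 glutathione S-transferases. GstE6, a detoxification enzyme gene, stood at 12.60 ± 0.04 (SD, n = 2) and GstD1 at 11.26 ± 0.06. Of 81 cytochrome P450 genes 28 passed, with Cyp6a20 at 10.24 ± 0.01 and Cyp6a17 at 9.83 ± 0.002. Of 31 genes named for the V-ATPase, which acidifies endosomes, 17 passed, with Vha16-1 at 12.22 ± 0.05.

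Of families linked to sensation or cuticle, 3 of 53 ionotropic receptors, 8 of 47 odorant-binding proteins, 4 of 27 pickpocket channels, 6 of 24 Osiris and 8 of 24 Tweedle genes passed. The ionotropic receptor gene Ir76a was at 7.57 ± 0.12 and the nicotinic acetylcholine receptor subunit gene nAChRbeta3 at 9.31 ± 0.03, where 3 of 9 subunit genes passed.

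X-linked genes above the floor had a lower median than autosomal ones, while X-linked genes as a whole had a higher one. Whether the higher median comes from the larger share of X-linked genes above the floor was not decided: with the shares made equal the difference over all genes was -0.21, but that value only restates the lower X levels already seen above the floor. Averaging over probe sets that miss the transcript is argued against for the lower median, which was -0.33 over genes with 1 probe set (central 95% of random sets -0.19 to 0.17). Whether it comes only from extra X-linked genes just above the floor cannot be told apart from a shift at all levels: the X share was higher by more than in the central 95% of random sets at a cutoff of 5 (2.68 points) and lower by more at 8 (-2.80), but within it at 6 (0.59), 7 (-1.94), 9 (-1.31) and 10 (-0.71). Among genes above the floor, X minus autosome was -0.06 at the 10th percentile of level, -0.35 at the 25th, -0.32 at the 75th and -0.36 at the 90th. These percentiles were not set against random sets, so they do not decide it. X dosage, gene content and probe affinity stay open, untested.

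Neighbouring genes shared their side of the floor in 65.2% of 11820 pairs, against a mean of 50.9% and a maximum of 52.3% in 1000 shuffles of the gene order within arms. The share was 60.0% for genes 2 places apart, 55.2% for 5 and 52.1% for 10, the last within the range of the shuffles. Chance order is thus argued against, and so are cross-hybridizing probe sets as the whole cause, with an excess of 13.6 points on probe sets without the s, x or a suffix. Tandem gene families cannot be told apart from other causes: the excess was 14.3 points without the 390 pairs of a common name stem, which were too few for their removal to decide, and families of genes with CG numbers were not removed. Overlapping transcripts and shared chromatin may both contribute and were not tested.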
